A study of Arabidopsis thaliana with 18 samples.

How the data were processed

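Ribosome footprints and RNA of 9-day-old seedlings were sequenced from Col-0, ceres-1 and ceres-2, with 3 libraries for each genotype and kind of library, 18 in all. Samples were grouped by genotype and kind of library from their labels. Libraries labelled as ribosome footprints form 1 kind, and the others were taken as RNA-seq because the series describes both assays and the file headers name total RNA. Nothing in the labels says whether the 3 replicates came from separate cultures. The authors' adjusted p-values can thus measure no more than the spread between these libraries, which can be technical. The list tests and Fisher's exact tests below compare genes and take no spread between libraries into account. Libraries were made with a ribosome profiling kit, per the labels' protocols.

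Reads were aligned with TopHat2 2.1.0, counted per gene with featureCounts 1.6.2 and compared with DESeq2, per the submitters' processing notes. The genome build, the annotation release, the strand setting, the treatment of reads with several matches and any shrinkage of fold changes are not given in the sources used here. The file analysed is the authors' deposited table of their own comparisons. It gives, per the file headers, a log2 fold change and an adjusted p-value for RNA, footprints and translational efficiency, each for ceres-1 and ceres-2 over Col-0, in 12 columns. The log2 fold changes were made by the authors from groups of libraries and hold no value per library. The adjusted p-values are the authors' and are left empty for part of the genes. The tool behind the efficiency columns is not given in the sources used here. The depth per library is unknown, and no interval or standard error was computed.

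The tests fixed before the data were examined were fits to values per library, with the 3 genotypes in 1 fit, a contrast of the mean of both alleles, a contrast of ceres-2 against ceres-1, and an interaction of library kind and genotype for efficiency. These could not be fitted to a table of comparisons. The authors' adjusted p-values were used in their place with a threshold of 0.05, and the contrast of ceres-2 against ceres-1 was left out. The mean of both alleles is the mean of the log2 fold changes. The size and direction of an efficiency change were taken as the footprint minus the RNA log2 fold change of the same allele, since the efficiency fold change column follows the footprint one. No paired analysis was possible because the table holds no values per library.

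Genes were named by a rule fixed at the same time and adapted to the table. Per layer it takes up to 10 genes per direction called in both alleles, by the mean log2 fold change, then fills up to 10 with genes called in 1 allele that have the same sign in the other. A planned minimum of mean counts could not be applied. CERES and up to 4 members of each gene list with the smallest adjusted p in either allele were also eligible. Of 27628 identifiers, 27420 matched the NCBI RefSeq gene table of assembly TAIR10.1, which was used for symbols, the order of neighbouring genes, coding length and coding GC only, so no coordinates are given. Symbols come from the lists, that table or the authors' deposited table.

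The 17 gene lists were also written then: 15 lists of 260 members in all and the genes encoded in each organelle. Of the 260 members, 237 had their symbol in the reference at the same locus, 22 had a symbol the reference lacks, and 1 was dropped because the reference gives its symbol to another locus. Lists were tested with cameraPR of limma 3.58.1 in R 4.3.3 on the mean log2 fold change of both alleles, with a preset correlation of 0.01, at least 3 members and Benjamini-Hochberg adjustment over the 16 lists tested per layer. The genes tested were the 12049 with an efficiency adjusted p in both alleles. The statistic is a fold change per gene, so an estimated correlation between genes, a rotation test and a count adjusted over the list alone could not be had. Tested on simulated data, with fold changes shuffled over the 12049 genes and 3 lists of at least 15 members shifted by 0.2 on the log2 scale, the procedure recovered 100% of shifted lists in RNA, 98.7% in footprints and 89.3% in efficiency. With a shift of 0.1 it recovered 52.7%, 50.7% and 20.7%. Shuffling removes any correlation between list members, and lists with fewer than 15 members were left out of the simulation. These shares therefore do not describe smaller lists or lists of correlated genes.

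Shared controls were simulated 100 times per comparison. For overlaps and shares of signs, each simulated list took as many genes as were called, by largest simulated fold change and not by adjusted p. The variance of a group mean was taken for each gene as 50% of the squared difference between the alleles' fold changes, which holds no Col-0 term but includes any true difference between the alleles. Tested on simulated data for the 12049 genes of the footprint comparison, an added shared variance of 0.04 was estimated as 0.0421, one of 0.01 as 0.00762 and one of 0 as -0.0011. Those data were drawn with the same assumed variance in every group, so they do not test whether the Col-0 libraries had it. Shares were compared with two-sided Fisher's exact tests in scipy 1.17.1. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6 were used, and trends over coding length or GC were removed with lowess for single genes and with loess for lists (span 0.3).

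Alternatives tried were other thresholds on the adjusted p, a minimum change of 1.5-fold, organelle genes left out, and, for lists, ranks, a correlation of 0.05, each allele alone, all genes with fold changes, removal of the length and GC trend, and the deposited efficiency column. All were chosen after the data were seen, because the alternatives fixed before need values per library.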

Results

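Ribosome profiling and RNA-seq were carried out on 9-day-old Arabidopsis seedlings of the wild type Col-0 and of ceres-1 and ceres-2, mutants of CERES, a plant protein that binds the cap-binding initiation factor eIF4E. Seedlings were collected 5 h after lights on (Zeitgeber time 5). The series holds 18 libraries, 9 of ribosome footprints and 9 of RNA, with 3 libraries per genotype and kind. The comparisons ask which mRNAs change in level, in ribosome occupancy or in translational efficiency (footprints relative to RNA) when CERES is disrupted. All values below derive from the authors' deposited table, which gives log2 fold changes of each mutant over Col-0 and adjusted p-values for 27628 genes. It has no values per library, so the depth is unknown and no SD or standard error can be given. A gene is called here when its adjusted p in that table is below 0.05.

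CERES (AT4G23840) itself was lower in both mutants. In the authors' deposited table its RNA log2 fold change was -4.43 in ceres-1 (adjusted p = 5.62e-08), a 21.6-fold lower level, and -2.92 in ceres-2 (adjusted p = 6.19e-05), a 7.59-fold lower level. Its footprint log2 fold changes in the same table were -3.77 and -3.16, without an adjusted p in either allele. The 3 genes on each side of CERES were not called in RNA in either mutant, and their RNA log2 fold changes in the authors' deposited table lay between -0.43 and 0.55.

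Few transcripts were called as changed in level, which does not show that the others were unchanged. The authors' deposited table calls 6 genes in ceres-1, 3 higher and 3 lower, among 24142 genes with an adjusted p for RNA. In ceres-2 it calls 26 genes, 22 higher and 4 lower, among 19000. In both alleles the calls include CERES, MRD1 (AT1G53480), OXS3 (AT5G56550) and MEE14 (AT2G15890). MRD1, a gene named for its fall in a methionine-accumulating mutant, had RNA log2 fold changes of -3.52 and -6.34 in the authors' deposited table (adjusted p = 1.53e-14 and 0.00214). Of its 6 neighbouring genes none was called in RNA, and the adjacent HEI10 (AT1G53490) was at -1.31 and -0.88 in the authors' deposited table. OXS3, a stress tolerance gene, rose by 1.77 and 2.11 on the log2 scale in the authors' deposited table (adjusted p = 0.0135 and 7.02e-05), and MEE14 by 0.77 and 1.26 (adjusted p = 0.0127 and 2.91e-09).

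The transcripts named next rose in ceres-2, and no enrichment of a function among the 22 rises was tested. ATHB2 (AT4G16780), a homeodomain factor induced by shade, had an RNA log2 fold change of 2.43 in ceres-2 in the authors' deposited table (adjusted p = 1.82e-19) against 1.03 in ceres-1 (adjusted p = 0.188). Its relative ATHB4 (AT2G44910) was at 1.77 in ceres-2 in the authors' deposited table (adjusted p = 0.0308), and the auxin synthesis genes YUC5 (AT5G43890) and YUC8 (AT4G28720) at 2.90 and 1.78 (adjusted p = 0.00774 and 3.01e-04). ACS8 (AT4G37770), an enzyme of ethylene synthesis, was at 2.36 (adjusted p = 0.0495) and AT5G21940 at 1.89 (adjusted p = 1.04e-13) in ceres-2 in the authors' deposited table. None of these genes was called in ceres-1, where the authors' deposited table gives log2 fold changes between 0.54 and 1.91 for them. The 2 remaining genes named as lower, BBX16 (AT1G73870) and AT1G64500, were at -0.85 and -1.02 in ceres-2 in the authors' deposited table (adjusted p = 0.0196 and 0.0349). AT1G75945 was called in ceres-2, at 5.65 in the authors' deposited table (adjusted p = 0.0495), with 5.94 in ceres-1 (adjusted p = 0.0514). AT3G15450 was called in ceres-1 alone, at 1.13 in the authors' deposited table (adjusted p = 0.00139), with 1.67 in ceres-2 (adjusted p = 0.469). Whether the alleles differ from each other was not tested, since the table holds no such contrast.

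More genes were called in ribosome footprints than in RNA, which does not show that more genes changed. Adjusted p-values lay close to their upper limit for 99.9% of tested genes in RNA of ceres-1 and 99.4% in ceres-2. In footprints these shares were 17.5% and 7.9%, and the power of the RNA and footprint tests was not compared. The authors' deposited table calls 64 genes in ceres-1, 35 higher and 29 lower, among 9967 with an adjusted p. In ceres-2 it calls 272 genes, 106 higher and 166 lower, among 14453. The median log2 change in the authors' deposited table was 0.77 in ceres-1 and 0.79 in ceres-2 for the genes called higher, and -0.63 and -0.53 for those called lower. At a change of at least 1.5-fold, 49 of the 64 calls in ceres-1 and 143 of the 272 in ceres-2 were left. In both alleles 15 genes were called higher and 10 lower, and 0 went opposite ways.

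The 10 genes with lower footprints in both alleles had various functions, and no enrichment of a function among them was tested. FAD2 (AT3G12120), the oleate desaturase of the endoplasmic reticulum, had footprint log2 fold changes of -0.98 and -0.94 in the authors' deposited table (adjusted p = 2.37e-05 and 6.63e-13). SLD1 (AT3G61580), a desaturase of sphingolipid bases, was at -0.71 in each allele in the authors' deposited table (adjusted p = 1.40e-04 and 5.03e-07). The thylakoid insertase ALB3 (AT2G28800) was at -0.45 and -0.65, the calcium-sensing protein CaS (AT5G23060) at -0.59 and -0.61, and TROL (AT4G01050) at -0.44 and -0.58 in the authors' deposited table. The plastid adenylate kinase AMK2 (AT5G47840) was at -0.55 and -0.54, and the sulfate transporter gene AT5G10180 at -0.61 and -0.95, in the authors' deposited table. The set is completed by XBAT31 (AT2G28840), AT4G18670 and AT3G56160, between -0.67 and -0.87 in the authors' deposited table. The RNA log2 fold changes of these 10 genes in the authors' deposited table lay between -0.17 and 0.18.

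Among the 10 genes with the largest footprint rise in both alleles were HSPRO2 (AT2G40000), a gene of basal resistance, with 0.998 and 1.71, and AT4G05070, a wound-induced polypeptide gene, with 0.99 and 1.21 in the authors' deposited table. ASN1 (AT3G47340), the asparagine synthetase induced in darkness, was at 0.83 and 0.63 in the authors' deposited table (adjusted p = 1.19e-04 and 1.69e-04). The calmodulin-like TCH3 (AT2G41100) was at 0.68 and 0.99, RAV2 (AT1G68840) at 0.56 and 0.94, MEE14 at 0.67 and 1.28, and AT1G31835 at 1.16 and 0.96 in the authors' deposited table. AT3G07350, AT5G19120 and AT1G32920 lay between 0.70 and 1.56 in the authors' deposited table.

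**Figure D1:**
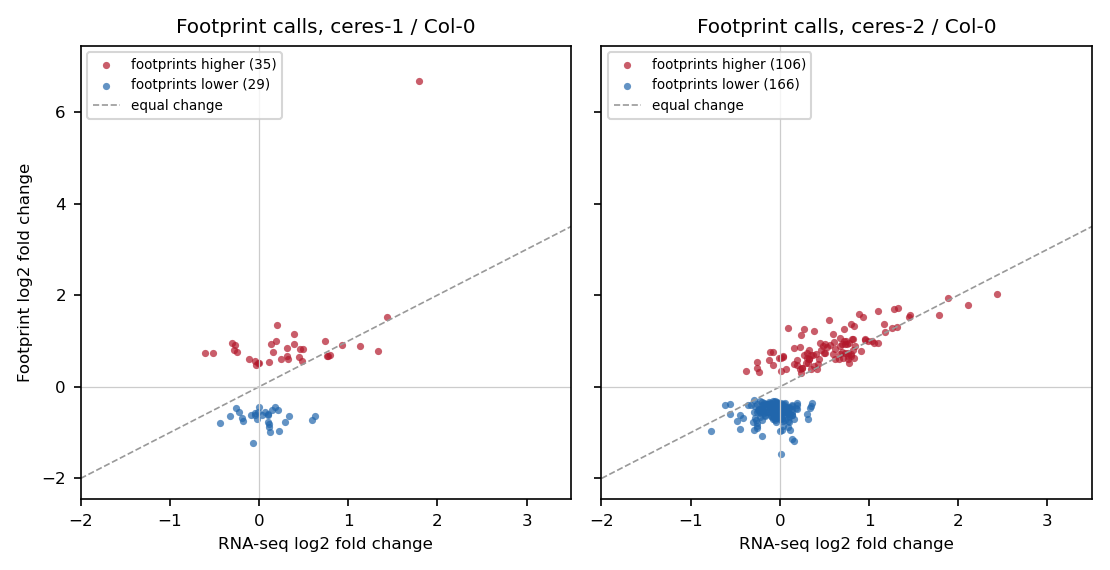
Log2 fold changes of RNA (x axis) and ribosome footprints (y axis) in the authors' deposited table for the genes called in footprints, ceres-1 over Col-0 at left and ceres-2 over Col-0 at right, with 1 point per gene and the dashed line marking equal change. In ceres-2 the 106 genes with higher footprints spread toward higher RNA (median RNA change 0.60, median footprint change 0.79) while the 166 genes with lower footprints gather around an RNA change of 0 (median -0.042), and the highest point at left is AT3G30320 at 6.68.

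The genes with higher and with lower footprints differed in what their RNA did. Of the 106 genes called higher in ceres-2 in the authors' deposited table, 76 had an RNA rise of at least 50% of the footprint change on the log2 scale, and their median RNA change was 0.60. Of the 166 called lower in the authors' deposited table, 16 had such an RNA fall, and their median RNA change was -0.042. The difference between these shares passed a two-sided Fisher's exact test across genes (odds ratio 23.8, p = 9.16e-27, adjusted p = 1.83e-26 over 2 tests). In ceres-1 the counts were 13 of 35 and 3 of 29 (odds ratio 5.12, Fisher's exact p = 0.0197, adjusted p = 0.0197), from the authors' deposited table. Genes are not independent replicates, and the odds ratio in ceres-1 no longer passed among genes with an adjusted p below 0.01 (6.40, Fisher's exact p = 0.193). Few of these genes were also called in efficiency in the same direction. In ceres-2 these were 4 of the 166 lower and 0 of the 106 higher genes, and in ceres-1 4 of 29 and 2 of 35.

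Translational efficiency was called at few genes. Fold changes between libraries scaled to each other are relative to the typical gene. A change of footprints or efficiency shared by most genes would therefore not be seen here. The median footprint minus RNA difference was -3.27e-04 in ceres-1 and -0.010 in ceres-2 across the 12049 genes with an efficiency adjusted p in both alleles. The authors' deposited table calls 13 genes in ceres-1, 8 higher and 5 lower, among 12120, and 5 in ceres-2, all lower, among 12188. Unadjusted p-values are not given there, so no count at an unadjusted threshold can be set beside the 0 genes called higher in ceres-2. Directions and sizes are given as the footprint minus the RNA log2 fold change, because the fold change columns headed as efficiency follow the footprint fold changes. FAD2 was lower in both alleles, with differences of -1.11 and -1.05 from the authors' deposited table (efficiency adjusted p = 0.0150 and 0.0469). AT3G03090, the vacuolar glucose transporter VGT1, was also lower in both, at -1.35 and -1.33 in the authors' deposited table (adjusted p = 0.0174 and 0.0495). In ceres-2 alone GASA4 (AT5G15230), AT1G70780 and AT3G47250 were lower, at -0.80, -1.28 and -1.02 from the authors' deposited table, with -0.52, -0.78 and -0.82 in ceres-1. Of the 13 calls in ceres-1, 6 were genes encoded in organelles, among them PSBM (ATCG00220, photosystem II) at -1.17 and PSAJ (ATCG00630, photosystem I) at -1.25, from the authors' deposited table. The mitochondrial genes RPL5 (ATMG00210), NAD3 (ATMG00990) and CCB382 (ATMG00830) were higher in ceres-1, at 1.29, 1.26 and 1.22 from the authors' deposited table. The nuclear genes called higher there were EBF1 (AT2G25490), an F-box protein of ethylene signalling, at 0.98, ATHB7 (AT2G46680) at 0.90, AT5G04020 at 1.01 and AT2G07725 at 1.27, from the authors' deposited table. AT2G07725 lies in a nuclear copy of the mitochondrial genome, so it can share reads with a mitochondrial gene and its value is uncertain. The nuclear gene AT2G37870 was lower in ceres-1, at -1.05 from the authors' deposited table (adjusted p = 0.0492).

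Nuclear photosynthesis genes had lower footprints, with individual calls in ceres-2. Of 42 genes of the light reactions, 7 were called lower and 0 higher in ceres-2 in the authors' deposited table, while 0 of 42 were called in ceres-1 and 0 in RNA in either allele. The light-harvesting genes LHCA4 (AT3G47470) and LHCB3 (AT5G54270) were at -0.97 and -0.74 in ceres-2 in the authors' deposited table (adjusted p = 1.25e-11 and 3.92e-09), with -0.44 and -0.35 in ceres-1 (adjusted p = 0.0563 and 0.154). LHCB5 (AT4G10340) was at -0.44 and LHCB1.5 (AT2G34420), which has near-identical copies that can share reads, at -0.48 in ceres-2 in the authors' deposited table. Of 18 genes of the Calvin-Benson cycle, 7 were called lower in ceres-2 footprints and 0 in ceres-1 in the authors' deposited table. The glyceraldehyde-3-phosphate dehydrogenase genes GAPA (AT3G26650), GAPB (AT1G42970) and GAPA2 (AT1G12900) were at -0.75, -0.52 and -0.42, and the aldolase FBA2 (AT4G38970) at -0.49, in ceres-2 in the authors' deposited table (adjusted p = 4.14e-08, 0.00138, 1.43e-04 and 3.05e-06). As a set, 32 of the 42 light reaction genes lay below 0 in the mean of both alleles (median -0.085, cameraPR adjusted p = 0.00535), as did 16 of the 18 Calvin-Benson genes (median -0.14, adjusted p = 0.00300). In ceres-1 alone neither set passed (adjusted p = 0.150 and 0.182), and the light reactions did not pass with a preset correlation of 0.05 (adjusted p = 0.104). In efficiency the light reactions passed (27 of 42 below 0, median -0.059, adjusted p = 0.0219, and 0.167 with a preset correlation of 0.05) and the Calvin-Benson cycle did not (15 of 18 below 0, adjusted p = 0.0646), although it passed with ranks (adjusted p = 0.0416) and in ceres-2 alone (mean -0.21, adjusted p = 0.0209).

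Genes induced by darkness and starvation lay higher as a set in RNA and in footprints among the genes tested for efficiency. The list did not pass among all genes with fold changes, a setting that changes both its members and the background. Of 9 members with a footprint adjusted p, 3 were called higher in each allele in the authors' deposited table, and none was called in RNA. ASN1 and SEN1 (AT4G35770) were called in both alleles, SEN1 at 0.65 and 0.60 in the authors' deposited table (adjusted p = 0.00850 and 0.0426). DIN10 (AT5G20250) was called in ceres-1, at 0.68, and DRM2 (AT2G33830) in ceres-2, at 0.73, in the authors' deposited table (adjusted p = 0.0256 and 0.0183). All 9 members lay above 0 in footprints (median 0.36, cameraPR adjusted p = 4.88e-08) and 8 of 9 in RNA (median 0.37, adjusted p = 3.41e-06), while efficiency did not pass (median 0.061, adjusted p = 0.590). Efficiency of this list passed as higher in ceres-1 alone (mean 0.26, adjusted p = 0.0443) and leaned lower in ceres-2 alone (mean -0.12, adjusted p = 0.531). With all 11 members that have fold changes, tested among all such genes, the list passed neither in RNA (mean 0.17 against 0.34, 3 members below 0, adjusted p = 0.655) nor in footprints (mean 0.25 against 0.41, 2 below 0, adjusted p = 0.453).

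Lists of abscisic acid, drought, heat shock and flavonoid genes were lower in RNA among the genes tested for efficiency. Each of these RNA calls was lost in ceres-1 or in ceres-2 alone, and none held across all genes with fold changes. Of 10 genes of abscisic acid, cold and drought response, 9 lay below 0 in RNA (median -0.28, cameraPR adjusted p = 3.95e-04) and 9 above 0 in efficiency (median 0.40, adjusted p = 5.74e-04). Since efficiency is the footprint minus the RNA change, a fall of RNA alone raises it, and the footprints of this list did not pass (adjusted p = 0.263). Their mean was -0.094 in ceres-1 alone (adjusted p = 0.342) and 0.27 in ceres-2 alone (adjusted p = 9.53e-04). The RNA call of this list was lost in ceres-2 alone (adjusted p = 0.136) and across all genes with fold changes (mean -0.14 against -0.27, cameraPR adjusted p = 0.715). COR15B (AT2G42530), KIN1 (AT5G15960) and COR6.6 (AT5G15970) were called higher in ceres-2 footprints, at 0.63, 0.66 and 0.63, and P5CS1 (AT2G39800), of proline synthesis, lower, at -0.45, in the authors' deposited table (adjusted p = 0.00417, 3.08e-04, 7.99e-04 and 0.0106). KIN1 and COR6.6 are similar neighbouring genes whose reads can be shared. All 5 tested genes of heat shock and the unfolded protein response lay below 0 in RNA (median -0.19, cameraPR adjusted p = 0.0248, and 0.0889 in ceres-1 alone) and above 0 in efficiency (median 0.42, adjusted p = 0.00379), with 0 single genes called. Their footprints did not pass (adjusted p = 0.122), except with ranks (adjusted p = 0.0248). Flavonoid and anthocyanin genes were lower in RNA (5 of 6 below 0, median -0.31, cameraPR adjusted p = 0.00381, and 0.173 in ceres-2 alone), while their footprints did not pass (mean -0.20, adjusted p = 0.0876), with a mean of -0.32 in ceres-1 alone (adjusted p = 0.00515) and -0.069 in ceres-2 alone (adjusted p = 0.824). The chalcone synthase CHS (AT5G13930) was called lower in ceres-1 footprints, at -0.64 in the authors' deposited table (adjusted p = 0.0168). Genes with a conserved upstream open reading frame had lower footprints (6 of 9 below 0, median -0.34, cameraPR adjusted p = 0.00241). That call was lost with ranks (adjusted p = 0.0873) and in ceres-1 alone (adjusted p = 0.0787), and in efficiency the list passed in ceres-2 alone (mean -0.28, adjusted p = 0.0209). VTC2 (AT4G26850), of ascorbate synthesis, was its called member, at -1.07 in ceres-2 in the authors' deposited table (adjusted p = 4.03e-05).

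Among the genes tested for efficiency, the mitochondrial genes lay higher as a set in RNA, footprints and efficiency. The chloroplast-encoded genes lay higher in RNA and lower in efficiency. Both alleles were compared with the same Col-0 libraries, so a shift in those libraries would appear in both alleles. Of 53 tested mitochondrial genes, 51 lay above 0 in footprints (median 0.65, cameraPR adjusted p = 5.30e-81), 36 in RNA (median 0.13, adjusted p = 6.16e-04) and 47 in efficiency (median 0.50, adjusted p = 9.69e-30). With a preset correlation of 0.05 the cameraPR adjusted p was 6.75e-35, 0.0413 and 7.85e-13. The test takes no spread between libraries into account. Here and for every other list, its p-values do not measure how well libraries repeat a shift. Single calls were fewer, with 3 of 26 mitochondrial genes called higher in ceres-1 footprints and 0 of 38 called in ceres-2 in the authors' deposited table. NAD9 (ATMG00070), a subunit of complex I, was at 0.77 in ceres-1 in the authors' deposited table (adjusted p = 7.27e-05) and at 0.50 in ceres-2 (adjusted p = 0.896). Of 88 chloroplast-encoded genes, 73 lay above 0 in RNA (median 0.22, cameraPR adjusted p = 1.94e-19) and 73 below 0 in efficiency (median -0.24, adjusted p = 1.04e-10), while footprints did not pass (median -0.041, adjusted p = 0.868). In footprints of ceres-1 alone the chloroplast list passed as lower (mean -0.090, adjusted p = 0.0403), and in ceres-2 alone it leaned the other way (mean 0.059, adjusted p = 0.0682). In ceres-1 footprints 4 chloroplast genes were called lower, with PSBM at -1.24 and PSBI (ATCG00080) at -0.73, in the authors' deposited table (adjusted p = 3.45e-17 and 2.37e-05). In ceres-2, 1 was called higher, RPS16 (ATCG00050) at 1.27, and 1 lower, PSBH (ATCG00710) at -0.40, in the authors' deposited table (adjusted p = 0.0190 and 0.00315).

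**Figure D2:**
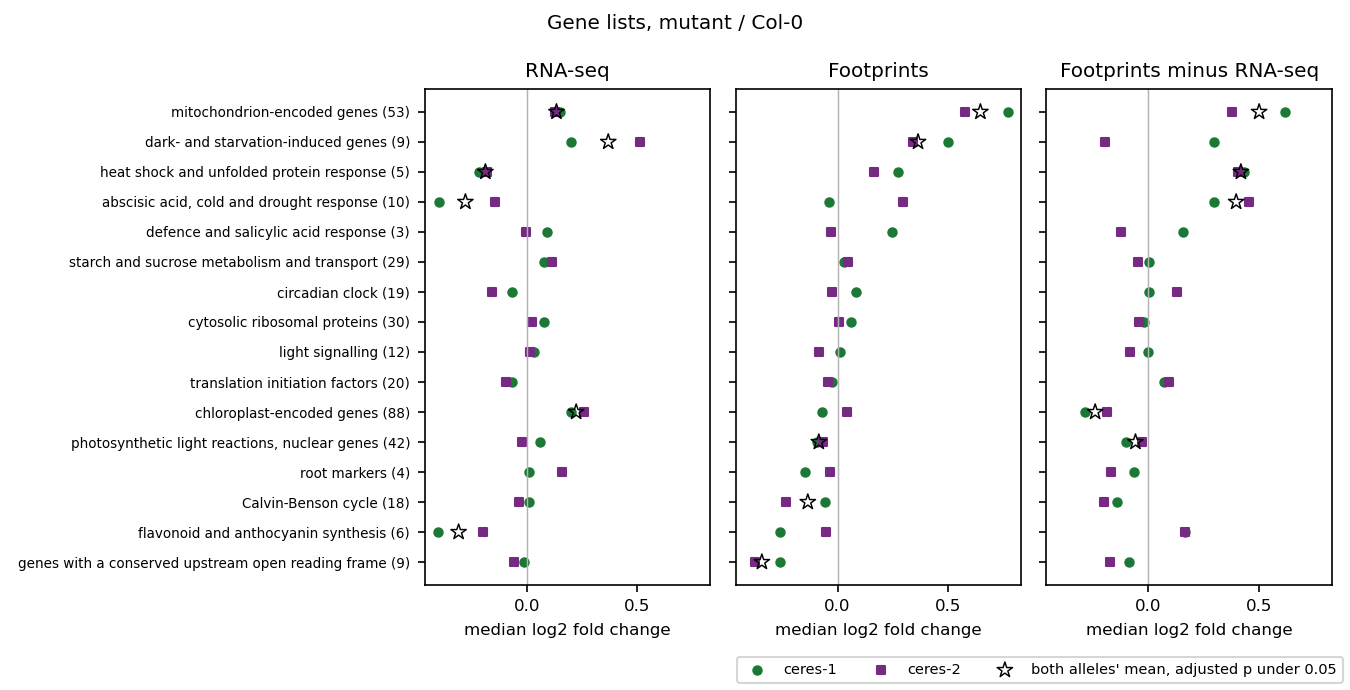
Median log2 fold change over Col-0 of each gene list (y axis, with the number of members tested) in RNA, in footprints and in their difference, as circles for ceres-1 and squares for ceres-2, with a star at the median of both alleles' mean where the cameraPR adjusted p of that mean is below 0.05. The mitochondrial genes stand highest in footprints (0.65 in the mean of both alleles), and the genes with a conserved upstream open reading frame lowest (-0.34).

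The remaining lists passed in no layer in the mean of both alleles. For cytosolic ribosomal proteins the cameraPR adjusted p was 0.132 in RNA, 0.868 in footprints and 0.576 in efficiency, and for translation initiation factors 0.319, 0.830 and 0.635. For the circadian clock these were 0.375, 0.868 and 0.590, although PRR5 (AT5G24470) and GRP7 (AT2G21660) were called higher, at 0.90 and 0.41, and LNK2 (AT3G54500) lower, at -0.66, in ceres-2 footprints in the authors' deposited table. In RNA of ceres-1 alone the ribosomal proteins passed as higher (adjusted p = 0.0431). The starch and sucrose list gave 0.0763, 0.263 and 0.680, and passed as higher in RNA with ranks (adjusted p = 0.0270), in ceres-2 alone (adjusted p = 0.0294) and with the coding length and GC trend removed (adjusted p = 0.0343), with the sucrose exporter SWEET12 (AT5G23660) called at 0.50 in ceres-2 footprints in the authors' deposited table. Light signalling gave adjusted p-values of 0.988, 0.868 and 0.909, with PIF4 (AT2G43010) called at -0.56 in ceres-1 footprints in the authors' deposited table. Defence genes gave 0.716, 0.199 and 0.590, with 0.0451 in footprints of ceres-1 alone, and root markers 0.733, 0.634 and 0.590. In footprints the clock and light signalling lists had medians above 0 (0.026 and 0.013) and means below it (-0.020 and -0.020), and in efficiency the same lists also differed in sign. The seed list had 1 tested member and was not tested. The list test compares genes and takes no spread between libraries into account. With every gene that has fold changes in the test, which also adds list members (the defence list goes from 3 to 13 and the mitochondrial list in RNA from 53 to 118), of the lists called above the chloroplast genes in RNA and efficiency and the mitochondrial genes in footprints and efficiency passed, the others did not, and the defence genes passed in RNA and footprints (adjusted p = 0.00101 and 7.35e-06).

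The alleles resembled each other, but both were compared with the same Col-0 libraries. Across the 12049 genes with an efficiency adjusted p in both alleles, the log2 fold changes of ceres-1 and ceres-2 correlated with r = 0.792 in RNA (rho = 0.774), 0.569 in footprints (rho = 0.535) and 0.705 in their difference (rho = 0.696), computed from the authors' deposited table. Unchanged groups simulated against shared controls gave mean r values of 0.499, 0.502 and 0.503, with highest values of 0.591, 0.575 and 0.577 in 100 draws. The simulation gives every group the same spread for a gene, so these mean r values follow from its setting and are not estimated from each layer. The covariance was 0.0350 in RNA against 0.00916 simulated, 0.0317 in footprints against 0.0243, and 0.0641 in the difference against 0.0275. The footprint r and covariance thus stayed below the highest simulated values (0.575 and 0.0319). The 15 shared footprint rises compare with 0.283 for independent lists and 13.2 simulated (highest 19), and the 10 shared falls with 0.477 and 15.9 (highest 23). The simulated means were 1.49 for the 2 shared RNA rises, 0.790 for the 2 shared RNA falls (highest 3 in each) and 1.4 for the 2 shared efficiency falls (highest 4). None of these overlaps exceeded the highest simulated from shared controls. The simulated lists took the genes with the largest fold changes, while the observed calls rest on adjusted p. The comparison therefore cannot decide whether the overlaps exceed what shared controls give. The Col-0 libraries could not be split without values per library, so the part of any excess that comes from them is unknown. Within an allele, RNA and footprint fold changes correlated across these genes with r = -0.0025 in ceres-1 (rho = -0.047) and 0.173 in ceres-2 (rho = 0.058).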

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

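All alternatives below were chosen after the data were seen. Every alternative fixed earlier was not run, because only fold changes and adjusted p-values per comparison were held: other size factors (RLE, or TMM over all 18 libraries), a DESeq2 or limma refit, other count filters, organelle genes left out of library sizes, fits on 2 genotypes, replicate blocks, leaving out each replicate, an estimated correlation, and the pseudocount, filter and read recovery meant for normalized values. Depth is unknown, so what it limits cannot be given.

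With an adjusted p under 0.01, the counts of changed genes were 3 in RNA of ceres-1 (6 at 0.05), 16 in RNA of ceres-2 (26), 27 in footprints of ceres-1 (64), 165 in footprints of ceres-2 (272), 3 in efficiency of ceres-1 (13) and 0 in efficiency of ceres-2 (5). These falls follow from the stricter threshold. Calls shared by the alleles were then 2 in RNA (4), 8 in footprints (25) and 0 in efficiency (2). Under 0.1, efficiency of ceres-1 had 40 calls and the footprints 40 shared calls. A minimum of 1.5-fold left 143 footprint calls in ceres-2, and leaving out organelle genes left 7 efficiency calls in ceres-1. The odds ratio for RNA behind the ceres-1 footprint calls was 6.40 under 0.01 (Fisher's exact p = 0.193), with fewer genes. The correlation of the alleles in efficiency was 0.518 across all genes with fold changes, against 0.705 in the core genes. Across all these genes it no longer exceeded the highest value simulated from shared controls.

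Across all genes with fold changes, 2 lists were called in RNA (6 in the core genes), 2 in footprints (5) and 2 in efficiency (5). That setting adds genes left without an adjusted p to the background and to the lists, and these were not varied apart. Efficiency had 3 called lists without organelle genes, where the organelle lists drop out, and 3 with the coding length and GC trend removed, which also covers nuclear genes only.

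Direction reversed for 28 of the list results, given here as the mean log2 fold change of the list. The cause was not tested, except for the efficiency column. The test compares a list with the other genes, so a direction can turn without a change of sign of the mean. In ceres-1 alone these were Calvin-Benson (0.018) and root (-0.014) in RNA, abscisic acid (-0.094) in footprints, and starch (0.0060) and light signalling (0.016) in efficiency. In ceres-2 alone they were light reactions (-0.033) and light signalling (0.018) in RNA, chloroplast (0.059) in footprints and dark (-0.12) in efficiency. With all genes they were Calvin-Benson (-0.027) and upstream reading frame (-0.024) in RNA, ribosomal proteins (0.0038) in footprints, and clock (0.010) and light signalling (0.024) in efficiency. With ranks it was light signalling in RNA (-0.0084) and footprints (-0.020), and without organelle genes light signalling in RNA (-0.0084). With the trend removed they were Calvin-Benson (0.012) and light signalling (0.018) in RNA, and initiation factors (0.0060), clock (0.0079) and light signalling (0.011) in footprints. With the efficiency column of the authors' deposited table they were ribosomal proteins (-0.0034), initiation factors (-0.042), clock (-0.023), starch (0.046), flavonoid (-0.21) and chloroplast (-0.014). That column follows the footprint change, and these means lie near the footprint means of the same lists (-0.20 for flavonoid, -0.015 for chloroplast). Of these 28, the chloroplast list in efficiency was the called one. The other list results kept their direction: 271 kept their side of the threshold, 18 passed it only under the alternative and 23 no longer passed it.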

Other observations

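All tests and lists in this part were chosen after the data were seen. A list of shade- and auxin-related genes was written after some of its members had been seen among the calls, so no p-value is given for it. Its 6 members with an efficiency adjusted p in both alleles lay above 0 in RNA (median 0.57) and in footprints (median 0.61). In the authors' deposited table, 5 of its 16 genes were called higher in RNA of ceres-2 and 0 in RNA of ceres-1.

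Lists of photorespiration and of chlorophyll synthesis were chosen in the same way. Of 13 photorespiration genes, 12 lay below 0 in footprints (median -0.18). In the authors' deposited table, 7 of them were called lower in ceres-2 footprints and 0 in ceres-1, with GLDP2 at -0.78 and GGT1 at -0.59 in ceres-2. Of 11 chlorophyll synthesis genes, 7 lay below 0 in footprints (median -0.062). GUN5 at -0.65 and CRD1 at -0.35 were called lower in ceres-2 footprints in the authors' deposited table, and 1 gene of that list was called higher in ceres-1.

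The following single genes were chosen after their values were seen. AT3G01345 had RNA log2 fold changes of -0.25 in ceres-1 and 5.77 in ceres-2 in the authors' deposited table (ceres-2 adjusted p = 0.00159). AT3G30320 had footprint log2 fold changes of 6.68 in ceres-1 (adjusted p = 0.0224) and 0.66 in ceres-2 in the authors' deposited table, where the latter has no adjusted p. ATMG00660 was called higher in efficiency in ceres-1, with footprint minus RNA differences of 1.69 and -0.28 from the authors' deposited table.

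The fall of footprints at 166 genes in ceres-2 was weighed against trends over the coding sequence. The genes called lower had a median coding length of 1428 nucleotides, those called higher 612, and all nuclear genes tested 1215. Across the nuclear genes tested, footprint changes fell with coding length in ceres-2 (rho = -0.214) and hardly varied with it in ceres-1 (rho = 0.027). Over coding GC, rho was -0.019 in ceres-2 and -0.165 in ceres-1. With the trend over coding length removed, the median log2 change of the nuclear genes called lower was -0.506 against -0.533 before, and with the trend over GC removed -0.524. A smooth trend across genes thus took little of the size of the fall. The genes were picked for low footprints, so this cannot show whether length or GC affected which genes were called. Loss of CERES may also lower these footprints in both alleles. Of the 166 genes, 98.8% were lower in ceres-1 too, against 84.4% simulated from shared controls (highest 89.8%). The overlap of calls was below the simulated mean. The simulated genes were taken by largest fold change and the observed ones by adjusted p, so these comparisons cannot decide for or against loss of CERES. Loss of CERES and the spread of the shared Col-0 libraries cannot be told apart without values per library, and the simulation holds an assumed noise.

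RNA fold changes were similar between the alleles but across all genes tested they did not follow footprint changes in ceres-1 (r = -0.0025) and followed them weakly in ceres-2 (r = 0.173), although the RNA of the genes with higher footprints in ceres-2 followed them (r = 0.772 across 106 genes). Coding length and GC took 2.02% of the variance of the mean RNA fold change, which argues against them as the cause. The covariance between the alleles exceeded the simulated one by 0.0258, which mRNA changes shared by both mutants could give. Spread among the 3 Col-0 RNA libraries could give it too, since mean RNA and mean footprint changes correlated with r = 0.0683 across genes, and these cannot be told apart because both mutants share these libraries.

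The efficiency fold change columns of the authors' deposited table may hold the footprint fold change, since at least 99.3% of genes in either allele lie within 0.1 of it. A change in efficiency would fall as RNA rises, but with the footprint change held the slope on RNA was 0.0040 in ceres-2 (0.0053 in ceres-1), which argues against that reading. The adjusted p-values beside them follow the size of the footprint minus RNA difference (rho = -0.956 and -0.931 across genes).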
